A study of Danio rerio with 16 samples.

How the data were processed

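The samples were pools of wild-type AB zebrafish, each holding 45 to 50 whole fish per the labels, raised in water with 0, 4, 40 or 400 ppb perfluorooctanoic acid (PFOA), a persistent surfactant of the perfluoroalkyl family. These doses are those of the labels, while the series text gives 40 ppb for the highest dose as well, so what is called 400 ppb rests on the labels. Exposure ran from about 1 h to 72 h after fertilization per the labels. Each dose had 4 replicates, which the labels call biological, and each replicate was hybridized to 1 array, so 16 arrays were analysed.

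The arrays were Agilent oligonucleotide arrays with a single dye, Cy3. The submitters' notes name Agilent Feature Extraction 12.0 for reading the scans, whereas the software was version 11.5.1.1 per the file headers. The authors deposited each spot's processed signal as an intensity that had been corrected for background and spatial trend within its array, with no scaling between arrays. Further steps behind these values are not given in the sources used here. The deposited value table of the series held the same intensity rounded to 3 significant digits, with differences of at most 0.498% from the scanner values. The authors' deposited table for each dose gave a log2 ratio per listed gene, and the test and threshold behind these lists are not given in the sources used here.

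Each array held 180880 spots, of which 176026 were not controls. Control spots and spots that the scanner software marked as uneven or as population outliers were left out. Intensities were log2 transformed, the spots of a probe were averaged, and the 75th percentile of the array was subtracted. Of 128291 probes, 106308 that were well above background on at least 4 of the 16 arrays were kept, and 21983 dimmer probes were left out. On at least 1 array, 4966 of the kept probes had no usable spot.

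Probes were named by matching their transcript accession to the RefSeq gene table of assembly GRCz12tu. This named 39952 probes, of which 38885 were kept, and gave 13304 measured genes. Probes known to the array by other kinds of accession stayed without a gene name and were tested all the same.

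All 16 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 coefficient per dose and 12 residual degrees of freedom. Each dose was compared with 0 ppb, the doses were compared with each other, and a moderated F test over the 3 dose contrasts and a slope over the order of the doses were computed. P values were two-sided and adjusted with the Benjamini-Hochberg method over all kept probes, with a threshold of 0.05. Counts of probes at an unadjusted p under 0.05 with at least a 1.5-fold difference are given as description. Errors beside log2 fold changes are limma's moderated standard error (SE), with 4 arrays per group where no other number is given.

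Per the file headers, the 4 arrays of a replicate number shared a slide, and a dose always lay at the same position of its slide. The replicate number therefore stands for the slide, and the same fit with the replicate number as a block (9 residual degrees of freedom) is given beside the counts and list calls. The labels do not say what else replicates of the same number share. Differences called slide differences below may therefore also be differences between biological replicates. The SE of single genes come from the fit without the block and so include differences between slides. Over all kept probes at 4 ppb the median SE was 0.193 without and 0.153 with the block. For lhb at 4 ppb it was 0.57 and 0.35, and for slc2a11l 0.31 and 0.32. A slide held 1 array per dose, so no test was possible within a slide. Replicate numbers also pair the arrays of different doses: for 400 and 0 ppb, the correlations of same-numbered arrays after removal of each dose's mean were 0.615, 0.531, 0.279 and 0.396, while for 40 and 0 ppb the lowest was −0.046 and for 4 and 0 ppb it was 0.098. The consensus correlation for the random form of the block was estimated on every 10th probe.

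Arrays were simulated from the mean and the spreads of each probe, with values drawn independently from probe to probe. Differences of 2-fold for 400 against 0 ppb, given to 50 probes, were called for 48% of them without the block and 62% with it. For 1.5-fold the shares were 8% and 22%, and for 4-fold they were 84% and 92%. The fit without the block made 0 false calls and the fit with it made 9 of 135. Probes of the real arrays are correlated, and the shares also depend on how many probes change at once. These shares and false calls may therefore not carry over to the real arrays.

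The 41 gene lists were tested per dose with limma's camera at its preset correlation of 0.01, adjusted over all lists and doses (123 tests). Camera with an estimated correlation and fry, whose mixed form asks whether members differ in either direction, were run beside it. Each gene stood once, by its brightest probe, whereas genes named by the rule below stood by a probe that was chosen for its small p among the gene's probes. Values without a usable spot were filled for the set tests, in 493 of the 13304 genes. For the normexp background correction used as an alternative, the median pixel intensity was taken and an offset of 50 was added. The offset draws log2 differences of dim probes towards 0, so counts at 1.5-fold with normexp are not comparable with those of other settings.

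The gene lists, the tests of the comparisons, the thresholds, the alternatives and the rule for named genes were fixed before the data were examined, apart from 1 alternative and some tests of explanations that are named as chosen later. Per dose the rule named up to 10 genes higher and 10 lower with an adjusted p under 0.05 whose arrays lay apart from the controls. With fewer than 10, it filled the list with the smallest unadjusted p among genes with at least a 1.5-fold difference. It also named up to 4 members per gene list, the 10 genes with the smallest p of the F test and of the slope, and the 10 genes with the largest values in the authors' deposited table for each dose. A listed gene that is withheld is not reported here.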

Results

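Transcript levels were measured in whole zebrafish larvae raised from shortly after fertilization in water without PFOA or with 4, 40 or 400 ppb of it. The series gives 4 dose groups of 4 arrays each, and each array carries the RNA of 1 pool of fish. Between 78.62% and 85.42% of the probes were well above background on an array, and 0 spots were saturated. The 75th percentile of the intensities ranged from 1149.3 in 0 ppb replicate 3 to 2837.9 in 40 ppb replicate 3. The share of spots marked as outliers ranged from 0.054% to 4.368%, with the highest share in 400 ppb replicate 4. Correlations between arrays of a dose lay between 0.976 and 0.99 across probes, which are not independent replicates. The number of arrays limits the precision of every value below.

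The arrays grouped by slide before they grouped by dose. Over the kept probes with values on all 16 arrays, the slide accounted for 53.9% of the variance and the dose for 11.7%. The dose share was about the mean share that relabelling the doses within slides gives (permutation test, p = 0.442). The slide share holds whatever the biological replicates of a number have in common, which cannot be told apart from the slide itself. After removal of each dose's mean, all 16 arrays were closest to an array of the same slide among the arrays of other doses. Arrays of the same dose were not searched, so this does not weigh slide against dose. The mean correlation of these deviations between doses was 0.449 within a slide and −0.149 between slides. Removal of the dose means itself brings the second value below 0 when the first is above it. The contrast of 0 ppb with the 3 exposed groups took 4.05% of the variance, and 81 of the 256 ways to pick 1 array per slide gave as much (exact permutation p = 0.316, smallest possible 0.00391).

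**Figure D1:**
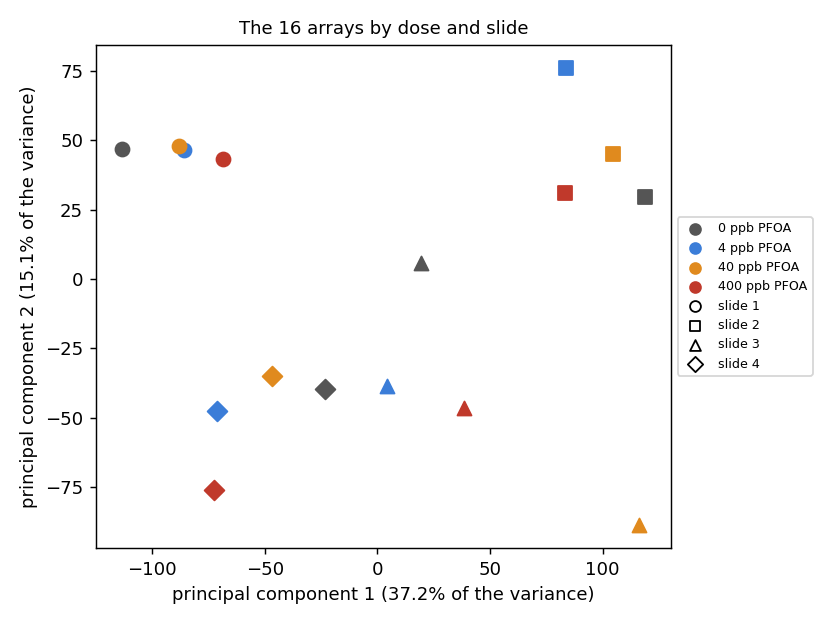
Principal components of the 16 arrays from the log2 intensities of the kept probes with values on all arrays, with the share of variance on each axis, colours for the dose and symbols for the slide. Component 1 holds 37.2% and component 2 holds 15.1% of the variance, and the arrays lie by slide more than by dose.

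The comparison of 4 ppb with 0 ppb asks which transcripts differ at the lowest dose. Higher values were those of lhb, the beta subunit of luteinizing hormone, and pias4b, a SUMO ligase, with log2 fold changes of 1.37 ± 0.57 and 1.19 ± 0.23 (SE, n = 4 per group). Both were higher on all 4 slides, although pias4b was well above background on 1 of the 4 control arrays and all 4 exposed arrays. The lhb probe was so on 2 control and 3 exposed arrays, and the values of its groups overlapped. Lower values were found for ttll11, a tubulin polyglutamylase, at −0.96 ± 0.30, and for cd83, a surface protein of antigen-presenting cells, at −0.79 ± 0.26 (SE, n = 4 per group). As ttll11 was well above background on 0 exposed arrays and 1 control array, no fold is given. The probe of cd83 was so on 1 array of each group, which leaves both values uncertain. None of these genes passed the adjusted test. With the normexp background correction, whose offset draws dim probes towards 0, the values of ttll11 and cd83 were both 0.01. Each value belongs to 1 probe, and the medians over all kept probes of a gene were 0.54 for pias4b, −0.01 for ttll11 and −0.43 for cd83.

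Further higher values at 4 ppb were those of slc2a11l, of the glucose transporter family, at 1.1 ± 0.31, of the zinc finger gene zbtb24 at 0.88 ± 0.27 and of the interleukin 21 receptor gene il21r.1 at 0.75 ± 0.36. The photoreceptor-related gene lrit3b had 0.71 ± 0.31, the ETS factor etv7 0.67 ± 0.30, the lymphocyte receptor gene cd226 0.66 ± 0.31 and the meiotic recombinase gene dmc1 0.62 ± 0.27. The log2 difference of ifng1, interferon gamma, was 0.78 ± 0.37, but it was well above background on 0 control arrays, so no fold is given. Among lower values, the odorant receptor gene or30bt3 had −0.99 ± 0.45, the neuropeptide Y receptor gene npy8ar −0.76 ± 0.34, and dlk1, a Notch-related ligand, −0.72 ± 0.31. The dlk1 probe was well above background on 0 exposed arrays and 1 control array, so no fold is given. The germ cell helicase gene ddx4 had −0.69 ± 0.31, with 0 exposed arrays and 1 control array well above background. With the normexp background correction and its offset the values of or30bt3 and ddx4 were 0.02 and 0.07. The cholesterol exporter gene abcg1 had −0.64 ± 0.36, the Nodal antagonist lft1 −0.62 ± 0.28, the negative elongation factor gene nelfa −0.59 ± 0.33, and the neuronal activity gene npas4a −0.59 ± 0.29. Over all kept probes of a gene the medians had the other sign for slc2a11l (−0.16) and npy8ar (0.10), with 1 of 3 probes each agreeing with the value above. They were 0.02 for cd226, −0.04 for abcg1, −0.06 for nelfa, −0.17 for ddx4, 0.23 for dmc1, 0.34 for etv7 and lrit3b, 0.38 for il21r.1, 0.41 for zbtb24 and −0.44 for or30bt3. The probe of slc2a11l was well above background on 1 control array, that of npy8ar on 1 exposed array, and that of or30bt3 on 1 array of each group.

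Of the 41 gene lists, 8 were called at 4 ppb by camera at its preset correlation, and 0 of them with the correlation estimated (adjusted p = 0.651 for the immediate early genes and 0.879 for the other 7). The 22 liver markers all had higher values, with a median log2 fold change of 0.13 (adjusted p = 5.88e-05), among them the fibrinogen chain gene fgb at 0.24 ± 0.12. Of the 22 exocrine pancreas markers, which encode digestive enzymes, 20 were higher (median 0.23, adjusted p = 0.000463), with slide means of 0.06, 0.66, 0.17 and 0.05. Of 26 antioxidant genes and Nrf2 targets, 23 were higher (median 0.07, adjusted p = 0.00268), though with a mean of −0.03 on slide 3. Of the 23 immediate early genes, many of which encode fast-responding transcription factors, 20 were lower (median −0.08, adjusted p = 7.37e-06), including egr4 at −0.44 ± 0.19 and npas4a. Of 23 cholesterol synthesis genes 15 were lower (median −0.03, adjusted p = 0.00336, slide means of −0.06, 0.06, −0.27 and −0.02), and of 16 endothelial markers 13 were lower (median −0.06, adjusted p = 0.0196). The 32 ribosomal protein genes were all higher (median 0.11, adjusted p = 0.0196), with slide means of 0.03, 0.39, −0.49 and 0.49. Of 31 respiratory chain genes, 27 were higher (median 0.06, adjusted p = 0.0196, slide means of 0.01, 0.26, −0.23 and 0.21), while quantile normalization gave a median of 0 and ended the call (adjusted p = 0.981). With the replicate block the respiratory chain was not called (adjusted p = 0.0597), quantile normalization also ended the calls of the ribosomal (median 0.02, adjusted p = 0.82) and endothelial lists (adjusted p = 0.072), and the mean of all probes ended the endothelial call (median −0.01, adjusted p = 0.549). The block added the steroid synthesis and stress axis list (median 0.08, adjusted p = 0.0473, and adjusted p = 0.9 with an estimated correlation).

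By limma, 0 probes passed the adjusted threshold at 4 ppb with or without the replicate block, and the smallest adjusted p was 1 without and 0.926 with it. At an unadjusted p under 0.05 there were 656 probes (477 higher, 179 lower) without and 2109 with the block. Leaving out 1 array moved the 656 to between 464 (0 ppb replicate 2) and 1532 (0 ppb replicate 1). For reference, 0.05 of the probes tested is 5315. This is not the number that unchanged groups give here, as probes are correlated and slide differences enter the SE without the block. Of the 656, 356 differed by at least 1.5-fold, 80.6% of them higher, against 55.6% of 374 with quantile normalization and 85.7% of 7 with the normexp background correction. Leaving out 1 array moved the number to 1076 without 0 ppb replicate 1, 678 without 0 ppb replicate 4, 616 without 4 ppb replicate 2 and 237, of which 53.6% were higher, without 0 ppb replicate 2.

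**Figure D2:**
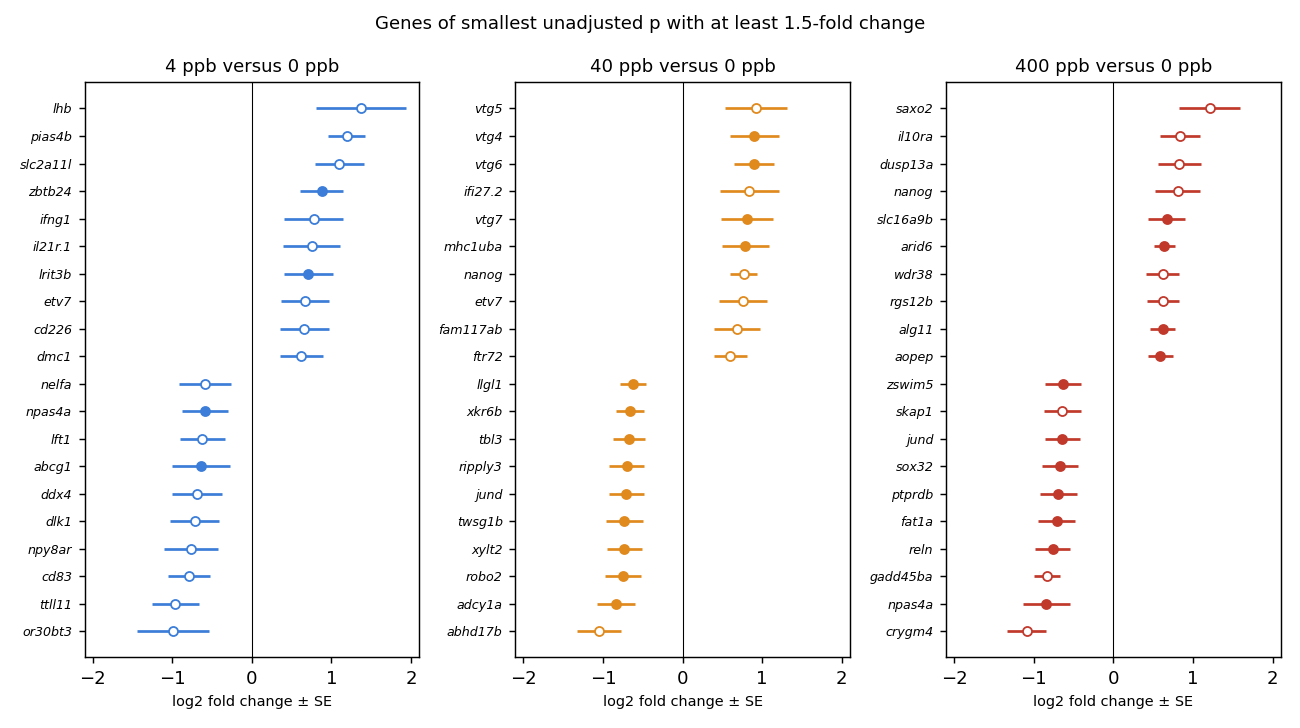
Log2 fold change against 0 ppb of the named genes at 4, 40 and 400 ppb, with error bars for the SE (4 arrays per group, but 2 for gadd45ba at 400 ppb) and open circles for genes that were not well above background on all 16 arrays. Values run from −1.09 for crygm4 at 400 ppb to 1.37 for lhb at 4 ppb, and none passed the adjusted test.

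The comparison of 40 ppb with 0 ppb asks which transcripts differ at the middle dose. Genes of the vitellogenin family, the precursors of egg yolk, stood among the higher values, with log2 fold changes of 0.92 ± 0.39 for vtg5, 0.90 ± 0.25 for vtg6, 0.90 ± 0.31 for vtg4 and 0.81 ± 0.33 for vtg7 (SE, n = 4 per group). By the brightest probe of each gene vtg5 had 0.69 ± 0.33, vtg7 0.61 ± 0.32, vtg6 0.35 ± 0.33, vtg4 0.31 ± 0.24 and vtg2 −0.12. The medians over all their kept probes were 0.18 for vtg5, where 8 of 12 were higher, 0.54 for vtg6, 0.31 for vtg4 and 0.32 for vtg7. The pluripotency factor gene nanog had 0.77 ± 0.17 and was higher on all 4 slides and with all 3 of its probes, whose median was 0.30. Lower values were those of abhd17b, a depalmitoylating enzyme, at −1.05 ± 0.28, of the adenylate cyclase gene adcy1a at −0.84 ± 0.24, and of robo2, the axon guidance receptor for Slit, at −0.75 ± 0.23 (SE, n = 4 per group). None of these genes passed the adjusted test, and abhd17b was well above background on 1 exposed array. The medians over all kept probes were −0.53 for abhd17b, −0.65 for adcy1a and −0.28 for robo2.

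Other higher values at 40 ppb were those of ifi27.2, induced by interferon, at 0.84 ± 0.37, the class I histocompatibility gene mhc1uba at 0.79 ± 0.29 and etv7 at 0.76 ± 0.30. The fixed list of 27 innate immune genes had a median of 0.01 at 40 ppb, with 16 higher and 11 lower (camera, preset correlation, adjusted p = 0.898). The finTRIM gene ftr72 had 0.60 ± 0.21 but −0.06 with the normexp background correction, and fam117ab had 0.68 ± 0.29. The proteoglycan enzyme gene xylt2 had −0.73 ± 0.22, the BMP modulator twsg1b −0.73 ± 0.23, the AP-1 component jund −0.71 ± 0.22 and ripply3, a partner of T-box factors, −0.70 ± 0.22. The values of tbl3, xkr6b and the cell polarity gene llgl1 were −0.67 ± 0.20, −0.66 ± 0.18 and −0.62 ± 0.16. Over all kept probes of a gene the medians were 0 for tbl3, −0.10 for twsg1b, 0.12 for fam117ab, 0.36 for ifi27.2, −0.39 for xkr6b and −0.48 for ripply3, so the size of the values of tbl3, twsg1b and fam117ab rests on few of their probes, although 2 of 3, 5 of 6 and 4 of 5 probes had the same sign. The ftr72 probe was well above background on 2 exposed arrays and 1 control array.

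At 40 ppb, 8 lists were called at the preset correlation and 0 with it estimated (adjusted p = 0.651 for the neurotransmitter systems and 0.879 for the other 7). Of 24 cell cycle genes, 23 were higher (median 0.17, adjusted p = 7.37e-06, slide means of 0.20, 0.09, 0.31 and −0.01), including the mitotic cyclin gene ccnb1 at 0.21 ± 0.10 and ccna2 at 0.27 ± 0.14. Neural lists had lower values: 26 of 31 genes of the neurotransmitter systems (median −0.14, adjusted p = 1.74e-05), such as the glutamate transporter gene slc17a7a at −0.28 ± 0.13, and 17 of 19 neuronal and synaptic markers (median −0.14, adjusted p = 0.000463), such as sypa at −0.33 ± 0.19. Their means were −0.36 and −0.44 on slide 3, and on slides 1, 2 and 4 they were −0.18, −0.04 and 0.04 for the neurotransmitter systems and −0.10, −0.01 and 0.07 for the neuronal markers. Of 28 photoreceptor and retina markers 24 were lower (median −0.11, adjusted p = 0.00592), with slide means of −0.59, 0.26, −0.11 and 0.03. Of the 23 immediate early genes 16 were lower (median −0.05, adjusted p = 0.0145), while scaling by the array median gave a median of 0.05. The 16 hatching gland and enveloping layer markers were all lower (median −0.14, adjusted p = 0.0325), as were 31 of 32 ribosomal protein genes (median −0.12, adjusted p = 0.00521). Of 26 skeletal muscle markers 23 were lower (median −0.14, adjusted p = 0.0325). For the muscle and ribosomal lists quantile normalization gave medians of 0.01 and 0.02, and it ended these calls and that of the hatching gland (adjusted p = 0.619, 0.819 and 0.337). These 3 lists were also lowest on slide 3, with means of −0.83, −0.92 and −0.76 for muscle, ribosomal and hatching gland genes. On slide 4 the same means were 0.29, 0.33 and 0.27. The 40 ppb array of slide 3 had 1.843% outlier spots and the highest 75th percentile of all arrays (2837.9). With the mean of all probes, the photoreceptor, muscle and hatching gland lists were not called (adjusted p = 0.0648, 0.0784 and 0.342). Median scaling kept all 8 calls but gave medians of −0.05 for both neural lists, −0.02 for photoreceptor, −0.04 for muscle and hatching gland, −0.03 for ribosomal and 0.27 for cell cycle genes. The replicate block kept all 8 calls and added the liver markers (median 0.10, adjusted p = 0.0397) and lens crystallins (median −0.09, adjusted p = 0.0333), both with an adjusted p = 0.9 when the correlation was estimated.

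By limma, 0 probes passed the adjusted threshold at 40 ppb, with a smallest adjusted p of 1 without and 0.611 with the replicate block. At an unadjusted p under 0.05 there were 3144 probes (631 higher, 2513 lower) without and 7005 with the block, where 0.05 of the probes tested is 5315. Single arrays decided on which side of 5315 the number lay, as it was 7225 without 40 ppb replicate 4, 6654 without 40 ppb replicate 1 and 1174 without 0 ppb replicate 3. Of the 3144, 945 differed by at least 1.5-fold, 16% of them higher, against 40.4% of 774 with quantile normalization, 46.1% of 814 with median scaling, 33.6% of 461 with array weights and 3.55% of 197 with normexp. Without 40 ppb replicate 3, 53.9% of 568 probes were higher, and leaving out another array moved the number to 2647 for 40 ppb replicate 1, 2498 for 40 ppb replicate 4, 1646 for 0 ppb replicate 4, 1458 for 0 ppb replicate 2 and 463 for 0 ppb replicate 3.

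The comparison of 400 ppb with 0 ppb asks which transcripts differ at the highest dose. The lowest value among the genes named for this comparison was that of crygm4, a lens crystallin, with a log2 fold change of −1.09 ± 0.25 (SE, n = 4 per group), lower on all 4 slides and with both of its probes (median −0.61), though well above background on 2 exposed arrays. The neuronal activity gene npas4a had −0.84 ± 0.29 and reln, a guide of neuron migration, −0.76 ± 0.22 (SE, n = 4 per group). The growth arrest gene gadd45ba had −0.83 ± 0.16 by a probe with values on 2 of the 4 arrays at 400 ppb, and −0.51 ± 0.12 by its brightest probe, which had values on all arrays. Higher values were those of saxo2, a microtubule protein gene, at 1.21 ± 0.38, of the interleukin 10 receptor gene il10ra at 0.84 ± 0.25, and of nanog at 0.81 ± 0.28 by another probe than at 40 ppb (SE, n = 4 per group). None passed the adjusted test. As il10ra was well above background on 0 control arrays, no fold is given, and the probes of saxo2 and nanog were so on 1 control array each. The medians over all kept probes were 0.54 for saxo2, where 1 of 2 was higher, 0.55 for nanog, −0.72 for npas4a and −0.13 for reln.

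Other higher values at 400 ppb were those of dusp13a, a phosphatase gene, at 0.83 ± 0.27, slc16a9b, of the monocarboxylate transporter family, at 0.67 ± 0.23, and the DNA-binding gene arid6 at 0.64 ± 0.13. The N-glycosylation gene alg11 and the G protein regulator rgs12b each had 0.62, with SE of 0.16 and 0.20, wdr38 had 0.62 ± 0.21 and the aminopeptidase gene aopep 0.59 ± 0.16. Lower values were those of the protocadherin gene fat1a at −0.71 ± 0.23, the receptor phosphatase gene ptprdb at −0.69 ± 0.23 and the endoderm factor sox32 at −0.67 ± 0.23. The values of jund, the T cell adaptor gene skap1 and zswim5 were −0.64 ± 0.22, −0.64 ± 0.23 and −0.63 ± 0.23, with skap1 well above background on 2 exposed arrays and 1 control array. Over all kept probes of a gene the medians were −0.13 for skap1, 0.05 for rgs12b, 0.12 for aopep, −0.33 for ptprdb and zswim5, 0.39 for slc16a9b and −0.42 for fat1a.

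At 400 ppb, 10 lists were called at the preset correlation and 0 with it estimated (adjusted p = 0.651 for the immediate early genes and 0.879 for the other 9). All genes, each by its brightest probe, had a median of 0.07 at this dose. Of the 23 immediate early genes 18 were lower (median −0.11, adjusted p = 4.62e-06, slide means of −0.21, −0.41, −0.16 and 0.18), including klf4 at −0.78 ± 0.31 and btg2 at −0.34 ± 0.17. Of 24 cell cycle genes 22 were higher (median 0.13, adjusted p = 0.01), with ccne2, a cyclin of the G1 to S transition, at 0.33 ± 0.16. Of 26 antioxidant genes and Nrf2 targets 23 were higher (median 0.14, adjusted p = 0.0274), among them the glutathione reductase gene gsr at 0.29 ± 0.15. Their slide means were 0.05, 0.10, 0 and 0.31, so slide 4 carried most of this difference, and 400 ppb replicate 4 was the array with most outlier spots. Of 13 myeloid markers 12 were higher (median 0.18, adjusted p = 0.0437), including coro1a at 0.21 ± 0.10. Lower were 21 of 26 skeletal muscle markers (median −0.12, adjusted p = 0.00123), 14 of 16 hatching gland markers (median −0.13, adjusted p = 0.0117) and 29 of 32 ribosomal protein genes (median −0.10, adjusted p = 1.74e-05). On slide 4 these 3 lists were higher, with means of 0.54, 0.51 and 0.54. Of 27 lens crystallins 18 were lower (median −0.05, adjusted p = 0.00749), with slide means of −0.23, −0.03, −0.36 and 0.30. The neuronal markers and neurotransmitter systems had medians of −0.01 each, but 8 and 14 members were higher (adjusted p = 0.0169 and 0.00571), and on slide 4 their means were 0.10 and 0.03. Scaling by the array median put the median of all probes at 0.13 at 400 ppb, against 0.04, and the medians of the lens, neuronal and neurotransmitter lists at 0.04, 0.08 and 0.08. It put those of the immediate early, muscle, hatching gland and ribosomal lists at −0.02, −0.03, −0.04 and −0.01, and those of the cell cycle, antioxidant and myeloid lists at 0.22, 0.23 and 0.27. Quantile normalization gave medians of 0.02 for muscle, 0.04 for ribosomal and 0 for lens genes. It ended these 3 calls (adjusted p = 0.74, 0.816 and 0.252) and those of the hatching gland, cell cycle and myeloid lists (adjusted p = 0.48, 0.127 and 0.087). Median scaling ended the neuronal and myeloid calls (adjusted p = 0.0516 and 0.0986), and the mean of all probes ended the neuronal, lens and hatching gland calls (adjusted p = 0.0609, 0.0516 and 0.124). The replicate block kept all 10 calls and added the targets of PPAR alpha and fatty acid oxidation (median 0.13, adjusted p = 0.0473, and adjusted p = 0.9 with an estimated correlation).

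**Figure D3:**
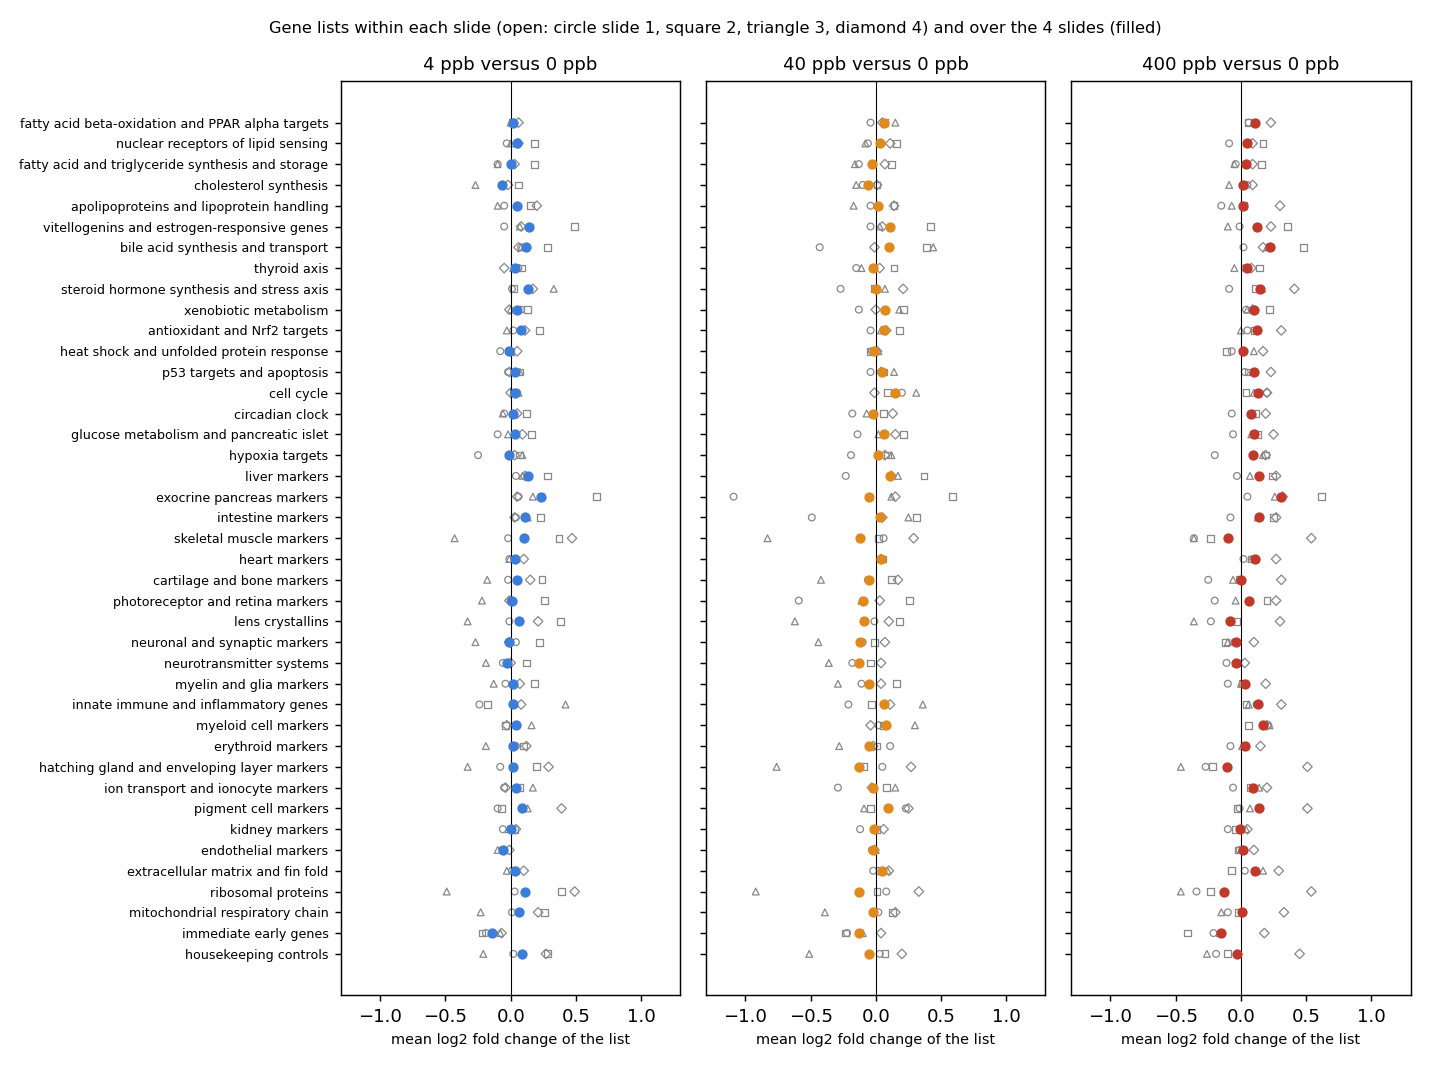
Mean log2 fold change against 0 ppb of each of the 41 gene lists at 4, 40 and 400 ppb, over the 4 slides (filled circles) and within each slide (open symbols). The means over the slides stay between −0.15 for the immediate early genes and 0.31 for the exocrine pancreas markers, both at 400 ppb, and single slides spread more widely.

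By limma, 0 probes passed the adjusted threshold at 400 ppb, with a smallest adjusted p of 1 without the replicate block and 0.324, for gadd45ba, with it. At an unadjusted p under 0.05 there were 2385 probes (1556 higher, 829 lower) without and 6903 with the block, where 0.05 of the probes tested is 5315. Without 0 ppb replicate 2 the 2385 became 4395, without 400 ppb replicate 1 3993 and without 40 ppb replicate 3 3702. Without 400 ppb replicate 4 it became 1448 and without 0 ppb replicate 3 1144. Of the 2385, 557 differed by at least 1.5-fold, 44.3% of them higher, against 75.1% of 790 with median scaling, 35.5% of 840 with array weights, 58.2% of 1367 with the replicate block, 26.7% of 86 with normexp and 13% of 131 with normexp and quantile normalization. Leaving out 1 array moved the number to 1264 (72.9% higher) for 0 ppb replicate 1, 1107 (27.9% higher) for 0 ppb replicate 2, 913 (30.8% higher) for 400 ppb replicate 1, 863 (57.8% higher) for 400 ppb replicate 2, 861 for 0 ppb replicate 4 and 370 for 0 ppb replicate 3, so the direction depends on single arrays as well as on the scaling and the block.

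PFOA is known as an activator of PPAR alpha, the receptor that controls fatty acid oxidation, so this list was examined at each dose. The 36 measured targets had medians of 0.01, 0.06 and 0.13 at 4, 40 and 400 ppb, with 31 members higher at 400 ppb (preset correlation, adjusted p = 0.0501), where the adjusted p was 0.879 with an estimated correlation. All genes, each by its brightest probe, had a median of 0.07 at 400 ppb, so part of the list's difference was shared with genes at large. For this list at 400 ppb, quantile normalization gave a median of 0.07 (adjusted p = 0.0722), while median scaling (median 0.22, adjusted p = 0.0424) and the mean of all probes (median 0.11, adjusted p = 0.0482) put it just past the threshold. At 400 ppb the values of acsl1a, which activates fatty acids, cyp4t8, ehhadh and eci2 were 0.24 ± 0.09, 0.30 ± 0.16, 0.19 ± 0.11 and 0.15 ± 0.08 (SE, n = 4 per group), but 1 of the 3 ehhadh probes was higher, and their median was −0.08. The slide means were 0.06, 0.06, 0.10 and 0.23. Adjusted over the list alone, 2 members over all lists and doses passed: gadd45ba among the p53 targets (−0.51 ± 0.12 by its brightest probe) and igfbp1b, which binds insulin-like growth factors, among the 11 hypoxia targets (0.50 ± 0.14), both at 400 ppb. The same igfbp1b probe did not pass among the 27 glucose and islet genes, so its passing depends on the size of the list. With the replicate block 12 members passed when adjusted over the list alone, and 0 passed over all probes in either fit.

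The tests over all doses asked whether a transcript differed at any dose or followed the order of the doses. On every slide the positions ran in the order of the doses. A slope over the doses can therefore not be told apart from a slope over the position on the slide. The smallest p of the slope belonged to gadd45ba, with −0.26 ± 0.05 per dose step and values of −0.29, −0.43 and −0.83 at 4, 40 and 400 ppb, by the probe with values on 2 arrays at 400 ppb. Next were arid6 with a slope of 0.19 ± 0.04, crygm4 with −0.36 ± 0.07 and values of −0.29, −0.58 and −1.09, and tbx20, a cardiac transcription factor, with −0.21 ± 0.05 and values of −0.05, −0.48 and −0.56. Smaller slopes were those of crtac1a at 0.18 ± 0.05, arrdc3a at 0.15 ± 0.04, the mitochondrial topoisomerase gene top1mt at 0.13 ± 0.03 and ftr14 at 0.12 ± 0.03. Negative slopes were also found for reln at −0.26 ± 0.07 and for pym1, which acts on exon junction complexes, at −0.13 ± 0.03. The F test ranked pias4b, arid6, il10ra, tbx20, gadd45ba, crygm4, nanog and alg11 ahead of scd, the stearoyl-CoA desaturase gene, with 0.36, −0.42 ± 0.20 and 0.24 at the 3 doses. At 40 ppb the median over the 7 kept scd probes was −0.01, and at 400 ppb the medians over all kept probes were −0.34 for tbx20 and −0.05 for pym1.

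By limma, 0 probes passed the adjusted threshold for the slope, with a smallest adjusted p of 0.925 without and 0.111 with the replicate block, and 0 for the F test, with 1 and 0.914. At an unadjusted p under 0.05 the slope gave 4628 probes (2711 with positive slopes) without and 10470 with the block, and the F test 1020 and 3739. While 0.05 of the probes tested is 5315, relabelling the doses within slides, with the block, gave medians of 4124 for the slope and 3739 for the F test.

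The doses compared with each other asked whether the response differed between doses. Differences of at least 1.5-fold at an unadjusted p under 0.05 were found for 547 probes between 40 and 4 ppb (33 higher at 40 ppb), 411 between 400 and 4 ppb (72 higher at 400 ppb) and 301 between 400 and 40 ppb (233 higher at 400 ppb). By limma 0 probes passed the adjusted threshold in any of the 3, with unadjusted counts of 1375, 1187 and 1109 without and 4166, 3704 and 3610 with the replicate block. No difference between doses was therefore shown for any gene named above.

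The log2 fold changes of the doses were correlated across probes, which are not independent and share the 0 ppb arrays. Pearson's r was 0.49 for 4 and 40 ppb, 0.48 for 4 and 400 ppb and 0.67 for 40 and 400 ppb, and 65.2%, 65.9% and 74% of probes had the same sign. Simulated groups without any difference against the same shared controls gave mean r of 0.46, 0.46 and 0.49, with central ranges of −0.33 to 0.78, −0.22 to 0.78 and −0.10 to 0.77. With the slides divided between the comparisons, so that each held 2 control and 2 exposed arrays, r was −0.10, −0.01 and 0.05, where 100 relabellings of the doses within slides gave a mean of 0 and central ranges of −0.18 to 0.17, −0.16 to 0.20 and −0.15 to 0.20. Agreement between the doses beyond what unchanged groups give was therefore not shown.

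The authors' deposited table held 37 entries for 4 ppb (21 higher), 79 for 40 ppb (11 higher) and 69 for 400 ppb (13 higher), for 36, 78 and 67 human gene symbols. Many entries, some with larger values, have no zebrafish gene name here, and the authors' deposited table is described by examples that have one. In the authors' deposited table for 4 ppb there were log2 ratios for mst1ra, a receptor tyrosine kinase gene, of 1.266, zbtb24 of 0.881 and ddx4 of −0.692. In the authors' deposited table for 40 ppb, nedd4a, a ubiquitin ligase gene, had −1.217, mst1ra 1.208, igf2r −1.049 and abhd17b −1.043. In the authors' deposited table for 400 ppb, spef2 had −1.062, adgra1a −0.919 and gadd45ba −0.893. The refit gave mst1ra, named by the authors' deposited table, 1.26 ± 0.34 at 4 ppb and 1.21 ± 0.34 at 40 ppb, and hmgb3a 0.82 ± 0.16 at 400 ppb where the authors' deposited table has 0.766 (SE, n = 4 per group). The probe of mst1ra was well above background on 4 of the 16 arrays, and those that the authors' deposited table names for igf2r and spef2 on 2 and 1.

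Of the probes named in the authors' deposited table, 4, 25 and 20 were tested at 4, 40 and 400 ppb, and 10, 7 and 4 were too dim. All tested ones had the same sign as in the authors' deposited table, and 4, 25 and 19 had an unadjusted p under 0.05, but by limma 0 passed the adjusted threshold with or without the replicate block. Within 0.01, the authors' deposited table matched a probe of the refit for 16 of 17 entries at 4 ppb, 37 of 40 at 40 ppb and 0 of 33 at 400 ppb. Over the 20 probes tested at 400 ppb, the median difference from the authors' deposited table was 0.0493 and the largest 0.265, while the correlation was 0.996. The refit was higher for rises and falls alike, as for hmgb3a (0.82 against 0.766) and jund (−0.64 against −0.688). Most of the mismatch of these probes was therefore a shift in 1 direction, whose cause was not tested. The lists share 12 genes between 4 and 40 ppb, 12 between 4 and 400 ppb and 34 between 40 and 400 ppb. Because the authors' deposited table was chosen on these arrays, its overlap with the refit is no independent evidence.

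**Figure D4:**
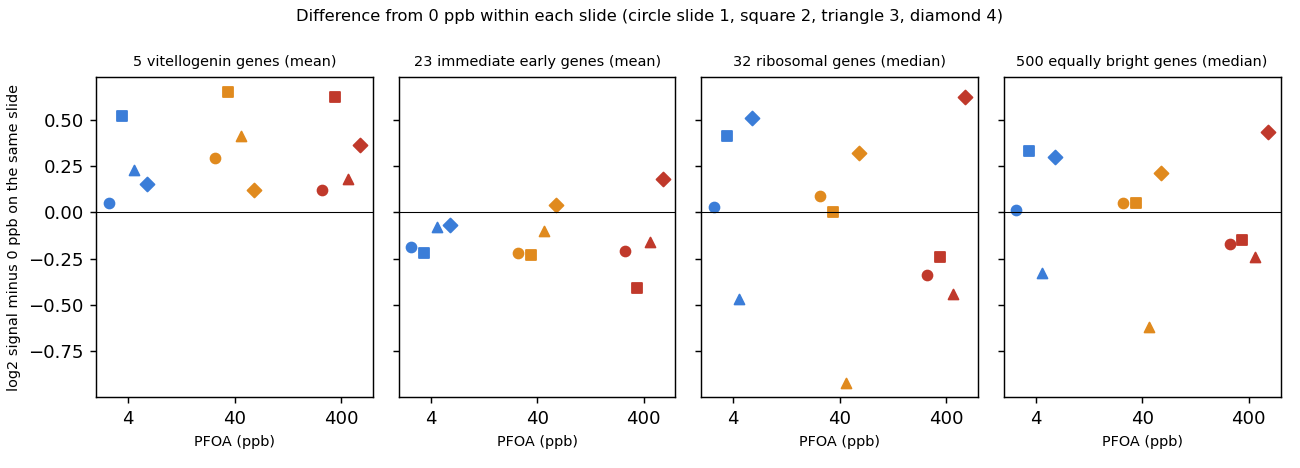
Difference in log2 signal from the 0 ppb array of the same slide, on each of the 4 slides (symbols) and at each dose, for 5 vitellogenin genes, 23 immediate early genes, 32 ribosomal protein genes and 500 other genes of like brightness. The vitellogenin mean is above 0 on every slide at every dose, and the ribosomal median at 400 ppb lies between −0.44 on slide 3 and 0.62 on slide 4.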

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

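The tests of array scaling and of slide position for the immediate early genes and of the liver share for the vitellogenins were chosen after the results were seen, and so was the test of the 5 vitellogenin genes, which were singled out after their values were seen.

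Immediate early genes, which respond within minutes to stimuli, had lower values than at 0 ppb at each dose, with medians of −0.08, −0.05 (0.05 with median scaling) and −0.11, and slide means above 0 at 40 and 400 ppb on slide 4 (0.04 and 0.18). Of the 256 ways to pick 1 array per slide, 8 gave a mean difference as large as −0.14 (exact permutation p = 0.0312), which meets the bound of 0.05 set in advance, but that bound did not count the 41 lists, over which the adjusted p was 0.559, and with this taken into account after the result was seen, other arrays standing apart as much stays open. Array scaling as the whole cause is argued against only weakly. Quantile normalization put the ribosomal list at 400 ppb from −0.10 to 0.04 but left the immediate early list at −0.13 relative to all genes (SD 0.11 over slides). This relative value was −0.12 in the main fit, and a factor per array cannot move it. The list stayed called at each dose (camera, preset correlation, adjusted p = 4.2e-05, 0.00598 and 4.29e-07), where an estimated correlation without this normalization gave 0.651 or more. Such calls decide little, as relabelling the doses within slides gave a median of 21 list calls beside the real 26. The −0.02 of median scaling, on which a first test decided nothing, came with a move of all genes from 0.03 to 0.09. Slide position, and with it any order of handling, cannot be told apart from dose, because 0 ppb lay at position 1 on 4 of 4 slides. A response to PFOA is a hypothesis that stays open beside these.

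The 5 measured vitellogenin genes, normally made in the liver under estrogen, had higher means than at 0 ppb on every slide at every dose, with medians of 0.22, 0.35 and 0.34, though vtg2 alone had −0.12 at 40 ppb. Because these genes were chosen for their values, the exact permutation p of 0.00391 for their mean difference of 0.31, the smallest possible, decides nothing, and the full list of 12 vitellogenin and estrogen-responsive genes had 0.13 (exact permutation p = 0.082, adjusted p = 0.559). The 22 liver markers had medians of 0.13, 0.10 and 0.14. They lay 0.16 lower than the vitellogenins over the doses and slides, just past the SD of 0.15 over slides, and at 400 ppb alone the difference was 0.14 with an SD of 0.23. Because the vitellogenins were chosen for their values, such a difference could arise from the choice alone, so a larger share of liver RNA stays open. Slide position cannot be told apart from dose here either, and near-identical vitellogenin copies may share probes. An effect of PFOA on yolk precursor genes therefore stays a hypothesis, found and tested on the same arrays.

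The 32 ribosomal protein genes had a median of −0.10 at 400 ppb (0.04 with quantile normalization), with slide medians of −0.34, −0.24, −0.44 and 0.62. The 500 other genes closest in mean signal had −0.04 where all genes had 0.07, within the spread of 0.49 over slides, so a difference between arrays that follows the brightness of probes may account for this list. On single slides these 500 genes had −0.17, −0.15, −0.24 and 0.43, the same signs as the ribosomal genes. What PFOA itself does to ribosomal genes stays open.

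Single arrays stood apart from the other 3 of their dose in 17 of 294 groups of values examined, where chance gives about 1 in 20. The measure is the array's gap to the nearest other, divided by the range of the group. The share of outlier spots was high in 0 ppb replicate 2 (1.08% against at most 0.07%, ratio 0.99), in 4 ppb replicate 2 (0.47%, ratio 0.89) and in 40 ppb replicate 3 (1.84%, ratio 0.89).

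Among list means, the circadian clock was high in 0 ppb replicate 1 (0.66 against 0.37, ratio 0.88). In 4 ppb replicate 2 the nuclear receptors of lipid sensing were low (−1.17 against −1.07, ratio 0.87) and the glucose and islet genes high (1.41 against 1.27, ratio 0.95). Endothelial markers were low in 4 ppb replicate 1 (−0.10 against −0.03, ratio 0.88). In 40 ppb replicate 3, fatty acid synthesis genes (−0.08 against 0.20, ratio 0.92) and myelin and glia markers (1.46 against 1.71, ratio 0.94) were low. In 400 ppb replicate 4, antioxidant genes (3.61 against 3.40, ratio 0.84) and photoreceptor markers (3.01 against 2.57, ratio 0.91) were high.

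Among named genes, etv7 was high in 0 ppb replicate 4 (ratio 0.84) and dlk1 was low in 0 ppb replicate 2 (ratio 0.85). In 0 ppb replicate 1, vtg6 was high (ratio 0.84) and fam117ab low (ratio 0.86). The value of ripply3 was high in 0 ppb replicate 3 (ratio 0.87), and that of ifi27.2 was low in 40 ppb replicate 1 (ratio 0.93).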

How the results depend on the processing

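Of the alternatives, the fit without the 3 arrays with most outlier spots (40 ppb replicate 3 and 400 ppb replicates 3 and 4) was chosen after seeing the data. The counts of probes past the adjusted threshold were 0 for each dose, the F test, the slope and the comparisons between doses, and stayed 0 in every setting run, including the replicate number as a block, fixed or random (consensus correlation 0.34). Only the threshold of an unadjusted p under 0.05 with at least 1.5-fold gave other counts: 356, 945 and 557 probes at 4, 40 and 400 ppb, 475 for the F test, 835 for the slope and 1259 between doses, as this threshold does not correct for the number of probes. Without the 3 arrays with most outlier spots these dose counts were 403, 535 and 813, of which 82.4%, 53.5% and 47.6% were higher. Array weights ran from 0.31 in 40 ppb replicate 3 to 2.22 in 0 ppb replicate 4.

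The 26 list calls became 0 with an estimated correlation, 16 with quantile normalization, 28 with median scaling, 22 with the mean of all probes and 29 with the replicate number as a block. Quantile normalization added antioxidant genes at 40 ppb and exocrine pancreas markers at 400 ppb (camera, adjusted p = 0.0239 and 0.0469). Median scaling added skeletal muscle and the steroid and stress axis at 4 ppb, lens crystallins at 40 ppb and PPAR alpha targets at 400 ppb (camera, adjusted p = 0.0041, 0.0391, 0.0146 and 0.0424). Of the 26, 12 were called with the block, quantile normalization, median scaling and the mean of probes alike. The respiratory chain at 4 ppb turned from 0.06 to 0 with quantile normalization. With the slides divided between the comparisons, so that each held 2 control and 2 exposed arrays, the correlations between doses moved from 0.49, 0.48 and 0.67 to −0.10, −0.01 and 0.05. This setting removed the shared controls and also left fewer arrays, and these were not told apart.

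For 227 values of named genes in 29 settings, 6531 alternatives were computed, of which 6517 kept their direction, 14 reversed and 0 passed the adjusted threshold. The genes were named for their small p on these same arrays, and the settings share most of their data. Kept directions are therefore little evidence for a difference. With normexp and the 75th percentile, ttll11 and cd83 were 0.01, ddx4 0.07, or30bt3 0.02 and ftr72 −0.06. With normexp and quantile normalization, b2m and ube2a at 400 ppb were 0 and −0.02. With array weights, cyt1 and gapdh at 40 ppb were 0.06 and 0.02. Without the 3 arrays with most outlier spots, nr1h4 and fabp2 at 400 ppb were 0 and −0.01. Leaving out 1 array gave mylz3 at 400 ppb −0.73 to 0.01 (highest without 0 ppb replicate 1), crygm2d3 at 400 ppb −0.73 to 0.01 (highest without 400 ppb replicate 2) and tuba1b at 4 ppb −0.03 to 0.26 (lowest without 4 ppb replicate 2). For these genes and for the list counts, the cause was not tested. The slide as a block was not run on its own, as it equals the replicate number. Signal over background limited 21983 probes, which were left out of the counts.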

Other observations

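The tests below that relabel or regroup the arrays were set before their results were seen, and the lists were fixed beforehand. Several lists that fit the known biology of PFOA were called at no dose by camera at its preset correlation. Nuclear receptors of lipid sensing (18 genes) had medians of 0.04, 0.03 and 0.05 at 4, 40 and 400 ppb, with the liver nuclear receptor gene hnf4a at 0.34 ± 0.20 at 40 ppb and rxrab at 0.28 ± 0.17 at 400 ppb. Fatty acid synthesis and storage (14 genes) had −0.03, 0 and 0.02, with elovl6, a fatty acid elongase, at 0.19 ± 0.09 at 400 ppb. Apolipoproteins (16 genes) had 0.06, 0 and 0.04, with the lipoprotein receptor gene scarb1 at 0.34 ± 0.17 at 400 ppb. The 8 bile acid genes had 0.12, 0.09 and 0.19, with the transporter gene abcb4 at 0.27 ± 0.14 at 400 ppb. The thyroid axis (17 genes) had 0.02, −0.01 and 0.05, and thrb, a thyroid hormone receptor, had −0.15 ± 0.11 at 40 ppb.

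The steroid and stress axis (21 genes) had medians of 0.08, 0.06 and 0.17 at 4, 40 and 400 ppb, with fdx1b, a ferredoxin of steroid synthesis, at 0.34 ± 0.11 at 400 ppb. Vitellogenins with estrogen-responsive genes (12 genes) had 0.15, −0.02 and 0.06. Xenobiotic metabolism (31 genes) had 0.05, 0.09 and 0.09, with cyp2k18 at 0.53 ± 0.22 at 40 ppb. Heat shock and unfolded protein genes (22 genes) had 0, 0 and 0.02, with sdf2l1 at 0.37 ± 0.15 at 400 ppb, where 1 control array gave no value. The p53 targets (17 genes) had 0.06, 0.06 and 0.11, with sesn1 at 0.24 ± 0.10 at 400 ppb. Circadian genes (28) had 0, −0.02 and 0.06, with the clock output gene dbpb at 0.50 ± 0.19 at 400 ppb. Glucose and islet genes (27) had 0.02, 0.06 and 0.11, with ins, insulin, at 0.26 ± 0.13 at 400 ppb, and hypoxia targets (11) had 0, 0.02 and 0.03. By fry in its mixed form with the replicate block, 3 of these groups were called: vitellogenins with estrogen-responsive genes at 40 ppb (adjusted p = 0.0049), p53 targets at 400 ppb (adjusted p = 0.0049) and glucose and islet genes at 400 ppb (adjusted p = 0.0485). Without the block fry called 0 in either form, and with it 0 in the directional form.

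Among tissue lists called at no dose by camera at its preset correlation on the brightest probe of each gene, medians at 4, 40 and 400 ppb were 0.10, 0.03 and 0.14 for intestine markers (pck1 0.43 ± 0.25 at 400 ppb; called at 4 ppb with the mean of all probes, adjusted p = 0.0413, but not by the brightest probe with an estimated correlation, adjusted p = 0.879), 0.04, 0.05 and 0.11 for heart markers (tnnt2a, cardiac troponin T, 0.23 ± 0.11 at 400 ppb) and 0.07, −0.08 and −0.02 for cartilage and bone. Myelin and glia markers had 0.01, −0.05 and 0.04, innate immune genes −0.04, 0.01 and 0.17 (the cytokine brake socs3a −0.42 ± 0.16 at 400 ppb), and erythroid markers −0.03, 0.01 and 0.05. Ion transport genes had 0.05, −0.01 and 0.07, pigment cell markers 0.05, 0.18 and 0.14 and kidney markers 0, −0.01 and −0.05. Extracellular matrix genes had 0.02, 0.07 and 0.10 (timp2b 0.56 ± 0.24 at 400 ppb), and housekeeping controls 0.10, −0.07 and 0.05, the last with 0.02 at 40 ppb under quantile normalization. Medians at 40 and 400 ppb depend on the scaling, as median scaling put the median of all probes at 0.06 and 0.13, against −0.03 and 0.04. At 400 ppb all genes, each by its brightest probe, had a median of 0.07, against which these lists and those above are to be read. Camera gave the direction of the innate immune genes at 400 ppb as lower (preset correlation, adjusted p = 0.551), although their median was 0.17.

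Regrouping the arrays showed whether the counts at an unadjusted p under 0.05 with at least 1.5-fold exceeded those of other splits, with values of unusable spots filled. At 4 ppb 35 of the 35 splits of the 8 arrays gave at least the real 358 probes (highest other 9162), at 40 ppb 27 of 35 gave the real 960 (13198), and at 400 ppb 27 of 35 gave the real 570 (10062), so chance is not excluded. The same holds between doses: 28 of 35 for 40 and 4 ppb (547, highest other 13389), 30 of 35 for 400 and 4 ppb (414, 8638) and 33 of 35 for 400 and 40 ppb (301, 14101). The highest other split in each of these 6 put the arrays of slides 1 and 4 against those of slides 2 and 3, a structure of the samples that follows the slides. Splits that do not part all slide pairs set slides against each other, while the real split balances them. The shares out of 35 therefore depend largely on the slide layout and decide little. With the replicate block, 3 of the 8 splits that part all pairs of 400 and 0 ppb gave at least the real 1369 probes (highest other 1966), too few splits for a share under 0.05. Without the block, the real split of 40 and 4 ppb ranked 1 among the 8 that part all slide pairs (547 against 544), and those of 4, 40 and 400 ppb against 0 ppb ranked 8, 7 and 2, again too few splits for such a share.

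Over all doses at an unadjusted p under 0.05, 96 of 100 regroupings gave at least the 1027 probes of the F test (highest other 24556), and 42 of 100 the 4751 of the slope (26294). These regroupings do not keep the slides balanced over the groups, as the real doses do. Relabelling the doses within slides, with the replicate block, gave as many as the real 3756 for the F test in 50 of 100 (highest other 10772). For the slope it gave as many as the real 10731 in 6 of 100 (highest other 18179, median 4124). Of the 100 relabellings 33 gave at least the real 26 list calls (highest other 41, median 21). Chance is therefore excluded for none of these counts.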
